A study of Mus musculus with 12 samples.

How the data were processed

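The deposited files, 1 per library, gave for each transcript an estimated count, a TPM value and an effective length, the usual output columns of kallisto. Per the submitters' processing notes, Trimmomatic 0.36 and kallisto 0.44 were used with GRCm38.p6, and which step each tool served is not given in the sources used here. Estimated counts made by the authors were the only values tested. Effective lengths in the deposited files entered only 1 alternative, as transcript length offsets. The deposited TPM values were used only to weight these lengths within a gene and to check the unit. Per the labels, tissue was spinal cord at postnatal day 10, RNA was extracted with Trizol, and libraries were prepared with a stranded mRNA kit. Each library came from 1 mouse per the labels, so 4 mice per group were independent replicates, and mouse numbers 1 to 4 were names only. The genotypes were used as labelled. The sex of the mice is not given in the sources used here.

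Transcripts were matched to GENCODE vM21 by identifier. Of 121843 transcripts 121104 matched and 739 did not, and the unmatched ones held 0.2185% to 0.2772% of counts. Counts were summed over 35675 genes and rounded. The 3 comparisons were RalA cKO against control, RalAB cKO against control and RalAB cKO against RalA cKO. The edgeR filter (minimum count 10, total 15) kept 13456 genes, and library sizes were scaled by TMM. All 12 libraries were fitted with a group mean each, with robust quasi-likelihood F tests in edgeR and Benjamini-Hochberg adjustment at 0.05. The common biological coefficient of variation was 0.199. A standard error was the log2 fold change divided by the square root of F. Principal components used log2 CPM with a prior count of 2. CPM values of single genes were scaled by TMM, and shares of counts were taken of the library total without it.

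Libraries of a group were compared for duplication with a chi-square over genes with at least 20 summed counts. The statistic per degree of freedom was 9.09 to 39.5, so every pair differed far beyond sampling noise and all 12 counted as separate. Those with control 1 were 27.4 to 39.5 and those with RalAB cKO 1 were 19.7 to 31.8. Mitochondrial reads were 1.45% to 2.64% of counts and the 10 highest genes held 13.1% to 15.1%.

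Genes were named by rule: the targets, the 10 protein-coding genes with the largest rise and fall among calls with a mean of at least 5 CPM over all 12 libraries, and up to 4 called members of each list with the smallest p. Predicted genes, Rik genes, Xist and Y-linked genes were not among the 10. For a list without a call the 2 most abundant members were looked at. Gene lists were written from general knowledge and numbered 30: exocyst subunits, Ral regulators and effectors, myelin proteins, late mature oligodendrocyte, newly formed oligodendrocyte, oligodendrocyte precursor, oligodendrocyte transcription factors, cholesterol synthesis, fatty acid and sphingolipid synthesis, integrated stress response, unfolded protein response, p53 targets, lysosome and autophagy, cell cycle, SNARE and Rab traffic, oxidative phosphorylation, interferon response, immediate early genes, microglia, reactive microglia, astrocyte, neuron, endothelial, pericyte and fibroblast, Schwann cell, ependymal, erythroid, mitochondrially encoded, and lymphocyte and granulocyte, with 1 further list that is not reported here. The lymphocyte and granulocyte list had 0 tested genes and gave no result. Each list was tested with camera in limma at a preset inter-gene correlation of 0.01, and beside it with a correlation estimated per list and with fry. Adjusted p-values of lists were taken over the 29 tested lists of a comparison. Counts adjusted over the list alone used the members of that list as the only tests. Median, mean and test differed in sign, among the lists reported, only in those that did not pass: p53 targets, Schwann cell and SNARE and Rab traffic in RalA cKO, transcription factors and pericyte in RalAB cKO, and transcription factors, unfolded protein response and SNARE and Rab traffic between the mutants.

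In a self-test with known changes planted in simulated counts, 2-fold changes were recovered in 80%, 80% and 86% of genes and 1.5-fold changes in 26%, 38% and 34%. Changes were planted only in genes with a mean of at least 5 CPM, so recovery of lower genes was not measured. False calls were 2.65%, 4.00% and 3.97% of all calls.

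The comparisons, tests, filter, lists, naming rule and alternatives were written before the data were examined. The alternatives were median-of-ratios scaling from DESeq2, library totals alone, no count filter or at least 1 CPM in 4 libraries, the DESeq2 test, limma-voom with and without quality weights, only the 2 groups compared, mouse number as a block, transcript length offsets, nuclear protein-coding genes only, summed Y-linked expression as a covariate, and each library left out in turn. For the shared changes they were an adjusted p under 0.1 and separate control mice for each mutant. Leaving out the 3 libraries with both Xist (at least 5 CPM) and Y-linked reads (at least 2 CPM), and the tests by chromosome position, were chosen after seeing the data. Genes with a close copy in the genome, such as Eno1b, Hba-a2, Cyp2j12, H2-D1 and histone genes, have uncertain levels because their reads can be divided between copies. Transcripts other than those of Rala and Ralb were not analysed here, and raw reads were not used here. Work used R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.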

Results

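RalA and RalB are small GTPases of the Ras family that bind the exocyst, a complex that tethers secretory vesicles at the plasma membrane. RNA was sequenced from spinal cord cells in which CnpCre, a recombinase expressed in myelinating glia, had turned on a tdTomato reporter. Cells of large size with red fluorescence were sorted at postnatal day 10, per the labels. There were 4 control mice, 4 mice labelled as lacking RalA in this lineage (RalA cKO) and 4 labelled as lacking both RalA and RalB (RalAB cKO), with 1 library per mouse. Libraries held 10.93 to 15.44 M estimated counts, and 12155 to 13165 genes reached 1 CPM (count per 1 M counts of a library). Genes for myelin proteins made up 13.1% to 15.1% of the counts of each library. Fold changes were expressed as log2 ± standard error with n = 4 mice per group, and adjusted p-values came from edgeR.

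The first principal component held 34.8% of the variance and set RalAB cKO apart (24.95 to 59.8) from RalA cKO (-25.9 to -9.95) and control (-34.2 to -23.2). Within the second component (17.6%), all 4 RalA cKO libraries lay at 14.6 to 41.1 and all control libraries at -48.2 to 0.14.

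**Figure D1:**
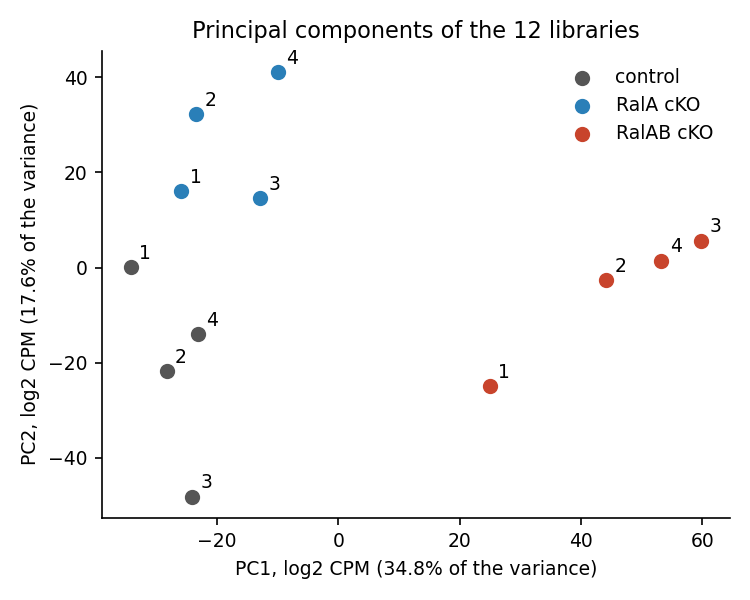
First and second principal components of log2 CPM in the 12 libraries, 1 point per mouse, n = 4 per group.

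Rala, the targeted gene of both mutants, was only modestly lower at the level of the whole gene. Its level was 35.5, 59.3, 47.0 and 56.3 CPM in control mice 1 to 4, 33.1, 42.4, 42.7 and 41.8 CPM in RalA cKO mice and 42.9, 32.2, 39.8 and 36.1 CPM in RalAB cKO mice. The difference from control was -0.31 ± 0.15 (adjusted p = 0.236) in RalA cKO and -0.39 ± 0.15 (adjusted p = 0.0832) in RalAB cKO. Ralb was 18.9, 15.1, 23.3 and 19.6 CPM in control, 17.5, 17.4, 13.4 and 13.5 CPM in RalA cKO and 14.03, 17.2, 15.9 and 16.1 CPM in RalAB cKO. Ralb differed from control by -0.28 ± 0.15 (adjusted p = 0.216) in RalAB cKO and from RalA cKO by 0.03 ± 0.15 (adjusted p = 0.936). For Rala the planned test thus did not reach the threshold, while transcript length offsets gave -0.58 in RalA cKO (adjusted p = 0.0305) and -0.63 in RalAB cKO (adjusted p = 0.00397). These offsets use a mean transcript length per gene weighted by TPM. Loss of a short transcript lengthens that mean, so the offset values are not independent of the short Rala transcript described below. Rala in RalAB cKO also passed with quality weights (-0.53, adjusted p = 0.00624), without control 1 (-0.52, adjusted p = 0.012) and without RalAB cKO 1 (-0.46, adjusted p = 0.0461). Ralb did not pass in any setting, so the counts did not show the RalB deletion given by the labels. Which exons the floxed alleles remove, and whether a shortened mRNA stays stable, is not given in the sources used here. The most abundant Rala transcript (ENSMUST00000009003, mean of 630 counts in control) did not pass in either mutant. It differed by -0.23 ± 0.17 in RalA cKO (adjusted p = 0.417) and -0.32 ± 0.17 in RalAB cKO (adjusted p = 0.206). A much less abundant short Rala transcript (ENSMUST00000223147) without the long last exon did separate the groups. It had 141.2 summed counts in control (10.75 to 76 per library), 0 in every RalA cKO library and 3.354 summed counts in RalAB cKO. It was at least 9.57-fold lower in RalA cKO with a floor of 3 counts per library (adjusted p = 0.00555). In RalAB cKO all of its counts came from 1 library. Summed counts scaled for library size were 44.0-fold lower there than in control (95% counting interval 14.8 to 216). That interval covers counting only and not the spread between mice. The edgeR fit gave -5.18 ± 0.89 (adjusted p = 0.0016).

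RalA cKO differed from control in 374 of 13456 tested genes (230 higher and 144 lower), and RalAB cKO in 2478 (1264 higher and 1214 lower). RalAB cKO and RalA cKO differed in 1551 genes (946 higher and 605 lower in RalAB cKO). Changes of at least 2-fold numbered 64 higher and 47 lower in RalA cKO, 550 and 536 in RalAB cKO, and 557 and 161 between the mutants. Among all 13456 genes, the values of the 2 groups did not overlap for 1535 (RalA cKO and control), 2587 (RalAB cKO and control) and 2325 (the mutants), where chance separates 2.86% of genes. Each count of changed genes (374, 2478 and 1551) was the largest of all 35 ways to divide its 8 libraries. The highest other count was 2 for RalA cKO against control, 1637 for RalAB cKO against control and 1 between the mutants. The 1637 came from exchanging control 1 with RalAB cKO 1. Scaling by library totals alone gave 426 genes in RalA cKO, 41.3% of them higher in place of 61.5%, with a median shift of -0.138. For RalAB cKO it gave 2421 genes, 41.4% of them higher in place of 51.0%, with a median shift of -0.0991.

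In RalA cKO, 9 of 25 late mature oligodendrocyte genes were higher and 7 of 24 cholesterol synthesis genes lower. Neither list passed with an estimated correlation between genes (adjusted p = 0.266 and 0.475). With fry by direction the first passed (adjusted p = 0.0202) and the second did not (adjusted p = 0.0978). Serpinb1a, a protease inhibitor of mature oligodendrocytes, rose by 2.55 ± 0.31 (adjusted p = 0.000655), and Hcn2, a pacemaker channel, rose by 1.45 ± 0.12 (adjusted p = 4.83e-06). Opalin, a paranodal membrane protein of central myelin, rose by 0.72 ± 0.13 (adjusted p = 0.00948). Lss, which cyclizes squalene epoxide to lanosterol, fell by 0.66 ± 0.12 (adjusted p = 0.0106). The genes that rose most were Eno1b (8.52 ± 1.26, adjusted p = 0.0112), a near-identical copy of Eno1 whose level is uncertain, and Ptgds (4.68 ± 0.76, adjusted p = 0.0158), a prostaglandin D2 synthase. Large rises were also found for the kelch-family gene Klhl30 (3.96 ± 0.40), the semaphorin Sema3b (2.82 ± 0.45), the matrix protein Adamtsl4 (2.19 ± 0.26), the neuronal enolase Eno2 (2.12 ± 0.46), the hyaluronan receptor Cd44 (2.07 ± 0.34), the polyadenylation factor Cpeb1 (2.01 ± 0.34) and the adaptor Sh2d3c (1.43 ± 0.35). The largest falls were in the endosomal protein Plekhf1 (-3.12 ± 0.16, adjusted p = 2.5e-08), the basement membrane protein Nid1 (-2.37 ± 0.23) and the ribonuclease subunit Pop4 (-2.03 ± 0.12). Next came the microglial genes Ly86 (-1.90 ± 0.31) and Siglech (-1.53 ± 0.31), the matrix protein Mgp (-1.87 ± 0.35), the phosphatase Ptpn14 (-1.45 ± 0.28), the transcription factor Tshz3 (-1.30 ± 0.22) and the G protein Gnal (-1.24 ± 0.28). Calls ended for Ptgds without control 2 (4.70) or control 3 (4.67), for Siglech without the same (-1.44 and -1.30), for Lss and Mgp without control 2 (-0.63 and -1.62) or RalA cKO 4 (-0.62 and -1.70), and for Ptpn14 without RalA cKO 4 (-1.33). Those of Gnal, Eno2 and Sh2d3c ended in 4, 8 and 8 of 12 runs with 1 library left out, the smallest values being -1.07, 1.71 and 1.09 without RalA cKO 4.

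Of 25 late mature oligodendrocyte genes 9 rose and 0 fell in RalA cKO (12 rose adjusted over the list alone; adjusted p = 8.96e-12, adjusted p = 0.266 with an estimated correlation). Examples were Serpinb1a, Pex5l 0.94 ± 0.13, Ndrg1 0.95 ± 0.15 and Sept4 0.77 ± 0.13. Of 25 myelin protein genes 2 rose and 0 fell (3 rose adjusted over the list alone; adjusted p = 0.00107, adjusted p = 0.552 with an estimated correlation), namely Opalin and Aspa 0.84 ± 0.17. Of 28 newly formed oligodendrocyte genes 4 fell and 0 rose (5 fell adjusted over the list alone; adjusted p = 0.00543, adjusted p = 0.327 with an estimated correlation): Cyfip2 -0.48 ± 0.10, Casr -0.54 ± 0.11, Bmp4 -0.67 ± 0.15 and Itpr2 -0.44 ± 0.11. Precursor genes had a median of -0.50 with 0 of 30 past the threshold (adjusted p = 0.00107, adjusted p = 0.65 with an estimated correlation), and of -0.312 without control 3. Of 28 cell cycle genes Tpx2, a spindle assembly factor, fell (-0.97 ± 0.22; 11 fell adjusted over the list alone; adjusted p = 2.31e-08, adjusted p = 0.475 with an estimated correlation). Without RalA cKO 4 the calls of Cyfip2 (-0.43), Casr (-0.53), Bmp4 (-0.62), Itpr2 (-0.39), Tpx2 (-0.93) and Aspa (0.82) ended, and without control 2 those of the same genes except Aspa (-0.49, -0.46, -0.67, -0.37 and -0.96). That of Aspa ended without control 3 (0.77).

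Of 24 cholesterol synthesis genes 7 fell and 0 rose in RalA cKO (8 fell adjusted over the list alone; adjusted p = 6.74e-06, adjusted p = 0.475 with an estimated correlation). These included Lss, Insig1 -0.58 ± 0.11 and Stard4 -0.78 ± 0.16. The summed share of these genes was 1.47 ± 0.0942% of counts in control and 1.12 ± 0.112% in RalA cKO (mean ± SD). Of 30 lysosome and autophagy genes 5 rose and 0 fell (5 rose adjusted over the list alone; adjusted p = 9.27e-05, adjusted p = 0.552 with an estimated correlation). Among them were Cd63 0.99 ± 0.17, Neu1 0.56 ± 0.12, Hexa 0.64 ± 0.14 and Ctsa 0.64 ± 0.15. Of 13 mitochondrially encoded genes 7 rose and 0 fell (10 rose adjusted over the list alone; adjusted p = 3.33e-13, adjusted p = 0.266 with an estimated correlation). Examples were mt-Nd3 1.18 ± 0.18, mt-Co3 0.93 ± 0.15, mt-Nd1 0.64 ± 0.14 and mt-Nd2 0.66 ± 0.15. Their share of counts was 1.73 ± 0.295% in control, 2.37 ± 0.253% in RalA cKO and 1.82 ± 0.202% in RalAB cKO. Nuclear genes of oxidative phosphorylation had a median of 0.17 with 0 of 28 past the threshold (adjusted p = 0.00543, adjusted p = 0.822 with an estimated correlation), and of 0.0995 without RalA cKO 1, which ended the call (adjusted p = 0.0774). Without RalA cKO 4 the calls of Lss (-0.62), Insig1 (-0.55), Stard4 (-0.72), Neu1 (0.51), Hexa (0.55), Ctsa (0.53), mt-Nd1 (0.61) and mt-Nd2 (0.58) ended.

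Of lists for other cell types, microglia genes held the only calls in RalA cKO. Of 20 microglia genes 3 fell and 0 rose (16 fell adjusted over the list alone; adjusted p = 4.54e-10, adjusted p = 0.475 with an estimated correlation): Ly86, Siglech and Itgam -1.10 ± 0.25. Siglech was not called without control 2 (-1.44) or control 3 (-1.30), and Itgam in 5 of 12 runs with 1 library left out (-0.92 without control 3). Microglia genes took 0.0572 ± 0.0213% of counts in control and 0.0315 ± 0.00735% in RalA cKO. Medians without a single call were -0.89 for 18 neuron genes (2 fell adjusted over the list alone; adjusted p = 0.000111, adjusted p = 0.552 with an estimated correlation) and -0.74 for 13 endothelial genes (4 fell adjusted over the list alone; adjusted p = 4.73e-05, adjusted p = 0.475 with an estimated correlation). The same held for 10 pericyte and fibroblast genes (-0.81; 5 fell adjusted over the list alone; adjusted p = 0.0199, adjusted p = 0.552 with an estimated correlation) and 16 interferon response genes (-0.46; 1 fell adjusted over the list alone; adjusted p = 0.0167, adjusted p = 0.552 with an estimated correlation). Single control libraries carried much of these falls. Mean log2 CPM in control 3 was 4.17 for neuron genes (2.62 to 2.82 in the other controls), 3.00 for endothelial genes (1.89 to 2.16) and 1.51 for pericyte genes (0.657 to 0.786). Without control 3 the medians were -0.313 for neuron, -0.455 for endothelial and -0.55 for pericyte genes, and the pericyte call ended (adjusted p = 0.125), as it did without RalA cKO 2 (adjusted p = 0.156). Interferon response genes were at 3.03 in control 2 and at 1.66 to 2.05 in the other controls, and without control 2 their median was -0.0406 and the call ended (adjusted p = 0.259). Without RalA cKO 3 it was -0.717.

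Lists that did not pass as a whole still held calls in RalA cKO: Acsl3 -0.77 ± 0.16 in lipid synthesis, Slc7a5 -0.71 ± 0.18 in the integrated stress response, Xbp1 0.72 ± 0.14 in the unfolded protein response and Phlda3 0.78 ± 0.15 among p53 targets. Among immediate early genes Arc 0.64 ± 0.16 rose and Nr4a1 -0.83 ± 0.19 fell. Without RalA cKO 4 all 6 calls ended (Acsl3 -0.68, Slc7a5 -0.63, Xbp1 0.63, Phlda3 0.70, Arc 0.49 and Nr4a1 -0.80), as they did without control 2. None of 9 exocyst subunits changed (Exoc4 -0.15 ± 0.09; Exoc6b 0.09 ± 0.12), nor did any of 18 Ral regulators and effectors, 25 oligodendrocyte transcription factors, 29 SNARE and Rab genes, 12 reactive microglia genes, 19 astrocyte genes, 12 Schwann cell genes (2 higher and 1 lower adjusted over the list alone), 5 ependymal genes or 6 erythroid genes.

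The RalA cKO counts were sensitive to single mice and to sex-linked reads: without RalA cKO 4 there were 85 genes, without control 2 there were 103, and with Y-linked expression as a covariate 111. Of 53 genes followed through the settings, 17 kept their call in every planned setting that held them. They included Klhl30, Sema3b, Cd44, Hcn2, Plekhf1, Nid1, Pop4, Ly86, Tshz3, Opalin, Serpinb1a, Pex5l, Ndrg1, Sept4, mt-Nd3 and mt-Co3. The last 2 were absent from the setting with nuclear protein-coding genes only.

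**Figure D2:**
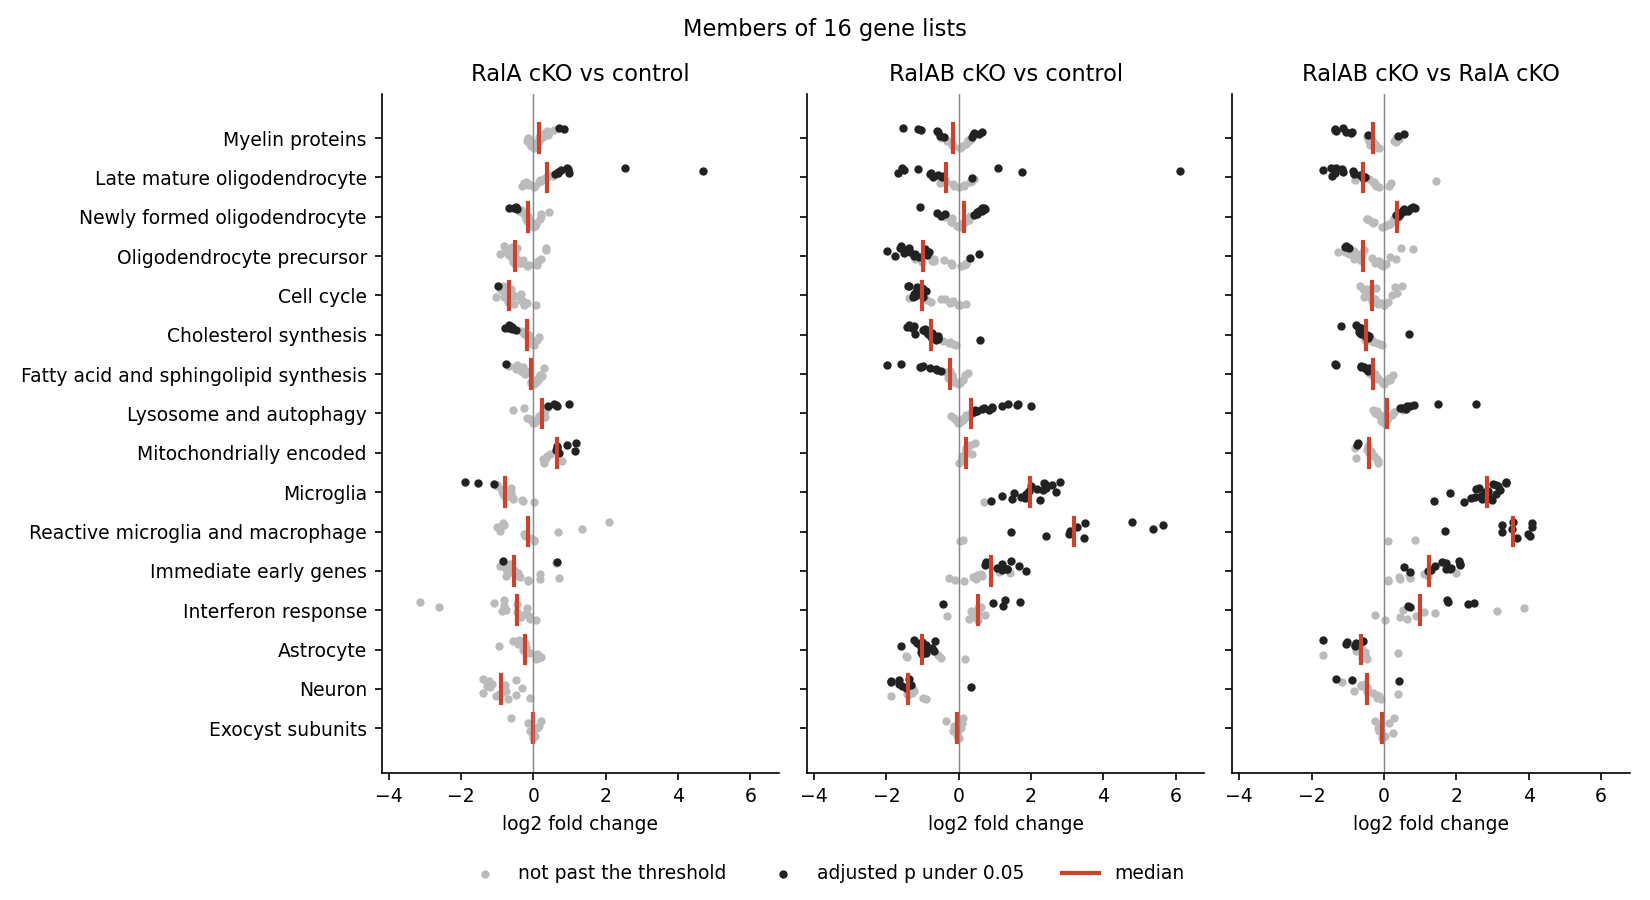
Log2 fold changes of the members of 16 gene lists in each of the 3 comparisons, 1 point per gene, with the median of each list as a red line, n = 4 mice per group.

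In RalAB cKO, 19 of 20 microglia genes and 10 of 12 reactive microglia genes were higher and 18 of 24 cholesterol synthesis genes lower. With an estimated correlation the adjusted p was 0.0829 for the microglia, reactive microglia and cholesterol lists. With fry by direction it was 0.000726, 0.000481 and 0.000481. Spp1, a secreted phosphoprotein of reactive phagocytes, rose by 5.64 ± 0.57 (adjusted p = 2.31e-05), and Trem2, a lipid receptor of microglia, rose by 2.81 ± 0.27 (adjusted p = 2.02e-05). The lanosterol synthase Lss fell by 1.38 ± 0.12 (adjusted p = 1.07e-05), and Scd1, a fatty acid desaturase, fell by 1.99 ± 0.19 (adjusted p = 1.76e-05). Mal, a proteolipid of compact myelin, fell by 1.53 ± 0.18 (adjusted p = 4.24e-05). The other genes that rose most were Eno1b (8.97 ± 1.26, uncertain as above), Ptgds (6.11 ± 0.80), the receptor Gprc5a (4.51 ± 0.93), the lipopolysaccharide co-receptor Cd14 (4.47 ± 0.42), Klhl30 (4.45 ± 0.40), the lysozyme Lyz2 (3.50 ± 0.34), the annexin Anxa2 (3.34 ± 0.44), the lipase Lpl (3.29 ± 0.39) and the vesicle protein Synpr (3.25 ± 0.47). The largest falls were in Cyp2j12 (-3.18 ± 0.46), a cytochrome P450 of a gene cluster with close copies, Mgp (-3.11 ± 0.38), Nid1 (-3.01 ± 0.24, adjusted p = 7.99e-06), the GTPase Rasl12 (-2.88 ± 0.44) and the securin Pttg1 (-2.48 ± 0.36). They were followed by the secreted protein Nell1 (-2.30 ± 0.26), the growth factor Fgf1 (-2.20 ± 0.23), the sorting nexin Snx22 (-2.17 ± 0.26) and the matrix protein Cnmd (-2.14 ± 0.30). Hba-a2 (-2.53 ± 0.65) shares its sequence with Hba-a1 and is uncertain, and its call ended without RalAB cKO 3 (-2.33).

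Microglial genes rose almost without exception in RalAB cKO. Of 20 microglia genes 19 rose and 0 fell (20 rose adjusted over the list alone; median 3.94-fold, adjusted p = 9.75e-33, adjusted p = 0.0829 with an estimated correlation). These included Trem2, Fcer1g 2.36 ± 0.26, C1qb 2.39 ± 0.24 and C1qa 2.58 ± 0.26. Their share of counts was 0.0572 ± 0.0213% in control and 0.219 ± 0.0496% in RalAB cKO. Of 12 genes of reactive microglia and macrophages 10 rose and 0 fell (10 rose adjusted over the list alone; median 9.10-fold, adjusted p = 3.09e-15, adjusted p = 0.0829 with an estimated correlation). Among them were Lgals3 4.79 ± 0.50, a galectin of phagocytes, Lyz2, Spp1 and Lpl. Of 30 lysosome and autophagy genes 14 rose and 0 fell (16 rose adjusted over the list alone; adjusted p = 2.52e-10, adjusted p = 0.298 with an estimated correlation). Examples were Ctsd 1.63 ± 0.16, Hexa 1.36 ± 0.15, Cd63 1.61 ± 0.17 and Ctsb 1.21 ± 0.14. Of 22 immediate early genes 12 rose and 0 fell (13 rose adjusted over the list alone; adjusted p = 1.7e-07, adjusted p = 0.298 with an estimated correlation). These included Zfp36 1.45 ± 0.21, Jun 0.74 ± 0.13, Arc 0.75 ± 0.16 and Ier2 1.20 ± 0.26. Of 16 interferon response genes 4 rose and 1 fell (6 rose and 1 fell adjusted over the list alone; adjusted p = 0.0124, adjusted p = 0.415 with an estimated correlation): B2m 1.29 ± 0.21, Psmb8 1.69 ± 0.37 and H2-D1 0.95 ± 0.22, the last with close class I copies, rose, and Stat2 -0.42 ± 0.12 fell. The interferon call ended without control 4 (adjusted p = 0.0551) or RalAB cKO 1 (adjusted p = 0.0704), and that of Stat2 in 5 of 12 runs (-0.36 without RalAB cKO 4).

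Of 24 cholesterol synthesis genes 18 fell and 1 rose in RalAB cKO (19 fell and 1 rose adjusted over the list alone; adjusted p = 7.47e-22, adjusted p = 0.0829 with an estimated correlation). Among them were Lss, Cyp51 -1.24 ± 0.12, Stard4 -1.44 ± 0.16 and Sc5d -1.25 ± 0.14. These genes took 1.47 ± 0.0942% of counts in control and 0.835 ± 0.0487% in RalAB cKO. Of 26 fatty acid and sphingolipid synthesis genes 9 fell and 0 rose (9 fell adjusted over the list alone; adjusted p = 2e-08, adjusted p = 0.206 with an estimated correlation). Examples were Acss2 -1.59 ± 0.14, Scd1, Scd2 -0.99 ± 0.12 and Fads2 -1.03 ± 0.13.

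**Figure D3:**
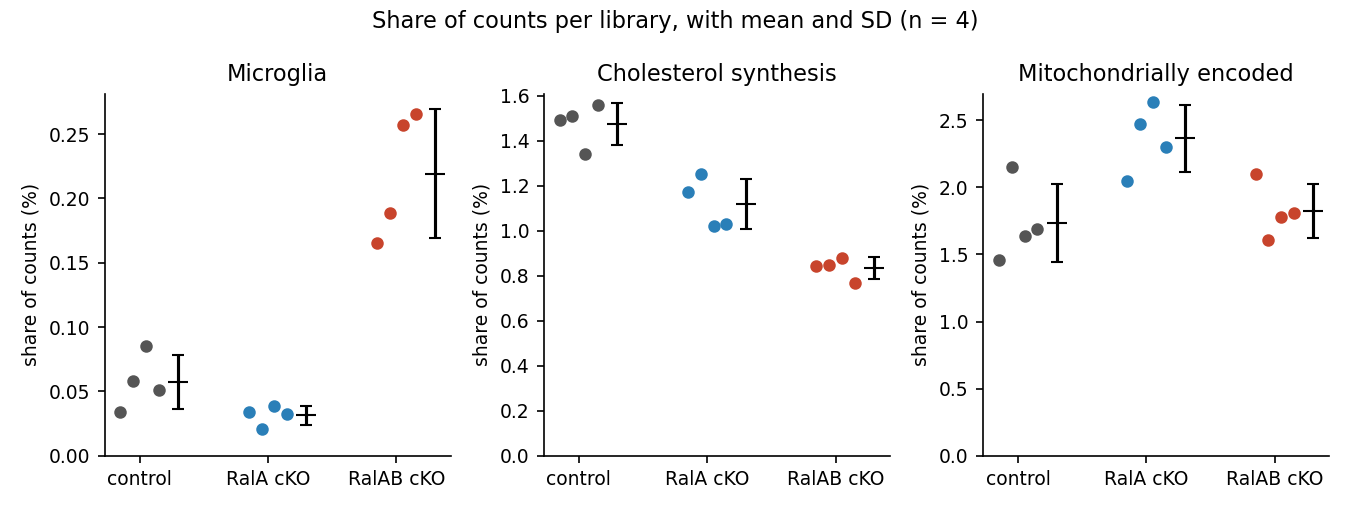
Summed share of counts of microglia, cholesterol synthesis and mitochondrially encoded genes in each library, with mean and SD, n = 4 per group.

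Of 30 oligodendrocyte precursor genes 16 fell and 2 rose in RalAB cKO (19 fell and 2 rose adjusted over the list alone; adjusted p = 1.7e-07, adjusted p = 0.298 with an estimated correlation). These included Megf11 -1.60 ± 0.27, Cspg5 -1.59 ± 0.29, C1ql1 -1.38 ± 0.28 and Rlbp1 -1.62 ± 0.34. Of 28 cell cycle genes 17 fell and 0 rose (18 fell adjusted over the list alone; adjusted p = 1.64e-08, adjusted p = 0.298 with an estimated correlation). Among them were Aurkb -1.37 ± 0.28, Rrm2 -1.40 ± 0.29, Ccnb1 -1.15 ± 0.24 and Ube2c -1.01 ± 0.22. Of 19 astrocyte genes 14 fell and 0 rose (15 fell adjusted over the list alone; adjusted p = 3.43e-08, adjusted p = 0.298 with an estimated correlation). Examples were Gja1 -1.25 ± 0.24, Aldoc -0.66 ± 0.13, Slc6a11 (2.00-fold lower) and Slc1a3 -1.17 ± 0.25. Of 18 neuron genes 8 fell and 1 rose (13 fell and 1 rose adjusted over the list alone; adjusted p = 5.63e-07, adjusted p = 0.298 with an estimated correlation). These included Uchl1 -1.37 ± 0.14, Tubb3 -1.65 ± 0.17, Nefh -1.86 ± 0.40 and Nefm -1.86 ± 0.44. Control 3 stood above the other controls in mean log2 CPM for neuron genes (4.17 against 2.62 to 2.82) and astrocyte genes (5.63 against 4.62 to 4.82), and without it the neuron median was -0.767 in place of -1.40 (adjusted p = 2.59e-05).

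Myelin and oligodendrocyte stage genes were split in direction in RalAB cKO. Of 25 myelin protein genes 7 fell and 5 rose (8 fell and 5 rose adjusted over the list alone; adjusted p = 0.228), with Mal, Omg -1.13 ± 0.15, Ermn -1.05 ± 0.18 and Mog -0.60 ± 0.13 among those that fell. Of 25 late mature genes 10 fell and 4 rose (12 fell and 6 rose adjusted over the list alone; adjusted p = 0.0956): Apod -1.57 ± 0.16, Gsn -1.11 ± 0.16 and Anln -1.50 ± 0.22 fell and Pex5l 1.08 ± 0.13 rose. Of 28 newly formed oligodendrocyte genes 9 rose and 4 fell (10 rose and 4 fell adjusted over the list alone; adjusted p = 0.077): Frmd4a 0.65 ± 0.11, Kif19a 0.70 ± 0.13 and Cemip2 0.72 ± 0.13 rose and Bmp4 -1.08 ± 0.16 fell. Of 25 oligodendrocyte transcription factors Tcf7l2 0.64 ± 0.14 and Myrf 0.40 ± 0.12, the activator of myelin genes, rose, and Sox8 -0.52 ± 0.12 and Nkx2-2 -0.59 ± 0.17 fell (adjusted p = 0.991). The calls of Myrf and Nkx2-2 ended in 6 and 4 of 12 runs with 1 library left out (0.33 and -0.52 without control 3).

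Single genes changed in lists that did not pass camera as a whole, though p53 targets passed fry by direction (adjusted p = 0.014). In the integrated stress response Atf3 2.54 ± 0.46, Cebpb 2.25 ± 0.49 and Ppp1r15a 1.13 ± 0.26 rose and Phgdh -0.70 ± 0.15 fell (4 up and 1 down of 20). Among 19 p53 targets 5 rose and 0 fell, with the death genes Bbc3 0.99 ± 0.20 and Hrk 2.20 ± 0.47 beside Btg2 1.67 ± 0.39 and Cdkn1a 1.87 ± 0.45. Ral partners Flna 0.69 ± 0.14, an actin crosslinker, and Rgl2 0.53 ± 0.11, a Ral exchange factor, rose (2 of 18). In vesicle traffic Vamp8 1.66 ± 0.31, Rab3d 0.77 ± 0.20 and Stx3 1.99 ± 0.52 rose (4 up and 2 down of 29). Further calls were Ramp2 -0.61 ± 0.18 (endothelial, 1 of 13), Anpep 3.84 ± 0.74 (pericyte, 1 of 10), Ngfr 1.57 ± 0.36, Sox2 0.31 ± 0.10 and Fcgrt 0.97 ± 0.32 (Schwann cell, 3 of 12), Nnat -0.51 ± 0.14 (ependymal, 1 of 5) and Hba-a2 (erythroid, 2 of 6 with calls). None of 9 exocyst subunits changed (Exoc4 0.13 ± 0.09), nor any of 20 unfolded protein response genes, 28 oxidative phosphorylation genes or 13 mitochondrially encoded genes. Calls ended without control 3 for Rab3d (0.62), without RalAB cKO 2 or 3 for Nnat (-0.45 and -0.48), and in 5, 8 and 8 of 12 runs for Ramp2, Sox2 and Fcgrt (-0.45 without control 1, 0.28 without control 4 and 0.83 without control 2). Of the genes followed, 88 kept their call in every planned setting. With 1 library left out, the count of changed genes lay between 1605 without RalAB cKO 4 and 3209 without RalAB cKO 1. With limma-voom quality weights it was 4071.

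Between the mutants, all 20 microglia genes were higher and 14 of 25 late mature oligodendrocyte genes lower in RalAB cKO, the first list past the threshold with an estimated correlation (adjusted p = 0.0292) and the second not (adjusted p = 0.0599). With fry by direction the adjusted p was 0.000182 and 0.000712. Ccl4, a chemokine of activated microglia, was 4.00 ± 0.59 higher in RalAB cKO (adjusted p = 0.000542), and Tnf, an inflammatory cytokine, was 3.72 ± 0.82 higher (adjusted p = 0.0147). Opalin was 1.13 ± 0.13 lower (adjusted p = 3.4e-05), and Klk6, a protease of mature oligodendrocytes, was 1.68 ± 0.20 lower (adjusted p = 6.57e-05). Further genes at the top were Ccl6 (3.77 ± 0.61), the inflammasome sensor Nlrp3 (3.74 ± 0.92), Tlr2 (3.72 ± 0.51), Cd83 (3.70 ± 0.70), the NF-kappa-B regulator Nfkbid (3.70 ± 0.64), Cd14 (3.69 ± 0.40), Plekhf1 (3.60 ± 0.16, adjusted p = 2.95e-09) and Lyz2 (3.58 ± 0.34). Lowest in RalAB cKO were Rasl12 (-2.56 ± 0.44), Cyp2j12 (-2.19 ± 0.46), the proteoglycan Spock3 (-2.07 ± 0.26), Fam178b (-1.83 ± 0.27), the collagen Col6a2 (-1.83 ± 0.23), the transferase Mgst3 (-1.79 ± 0.18), Snx22 (-1.72 ± 0.26), the motor Myo1e (-1.67 ± 0.15) and Pttg1 (-1.65 ± 0.36). The Tnf call ended without RalA cKO 1 (3.74, adjusted p = 0.052), without RalA cKO 2 (3.56, adjusted p = 0.0554) and with limma-voom. That of Nlrp3 ended without any 1 of RalA cKO 1 to 4 (3.94, 3.77, 3.72 and 3.53) and with limma-voom, and its value was 2.42 without RalAB cKO 4.

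All 20 microglia genes rose in RalAB cKO relative to RalA cKO (20 rose adjusted over the list alone; median 7.15-fold, adjusted p = 0.0292 with an estimated correlation). Among them were Fcer1g 3.37 ± 0.27, Ly86 3.38 ± 0.31, C1qb 3.01 ± 0.25 and Trem2 3.11 ± 0.27. Of 12 reactive microglia genes 10 rose and 0 fell (10 rose adjusted over the list alone; median 11.8-fold, adjusted p = 0.0296 with an estimated correlation). Examples were Lyz2, Lgals3 4.10 ± 0.48, Lpl 3.27 ± 0.39 and Clec7a 4.08 ± 0.54. Of 22 immediate early genes 13 rose and 0 fell (15 rose adjusted over the list alone; adjusted p = 1.76e-12, adjusted p = 0.149 with an estimated correlation). These included Zfp36 2.09 ± 0.22, Ier2 1.62 ± 0.27, Klf2 1.73 ± 0.32 and Ier3 2.11 ± 0.38. Of 16 interferon response genes 6 rose and 0 fell (7 rose adjusted over the list alone; adjusted p = 1.51e-06, adjusted p = 0.149 with an estimated correlation). Among them were B2m 1.74 ± 0.21, H2-D1 1.77 ± 0.22, Psmb8 2.50 ± 0.39 and Bst2 2.32 ± 0.43. Of 30 lysosome genes 9 rose and 0 fell (10 rose and 1 fell adjusted over the list alone; adjusted p = 0.000292, adjusted p = 0.522 with an estimated correlation). Examples were Ctsd 1.49 ± 0.16 and Ctsb 0.85 ± 0.14. Of 20 integrated stress response genes 5 rose and 1 fell (7 rose and 1 fell adjusted over the list alone; adjusted p = 0.0385, adjusted p = 0.499 with an estimated correlation): Cebpb 3.11 ± 0.54, Atf3 2.59 ± 0.47 and Vegfa 0.62 ± 0.15 were among the 5 and Phgdh -0.80 ± 0.15 fell. This call ended without RalA cKO 3 (adjusted p = 0.0941).

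Of 28 newly formed oligodendrocyte genes 14 were higher and 0 lower in RalAB cKO than in RalA cKO (17 rose and 3 fell adjusted over the list alone; adjusted p = 0.0296 with an estimated correlation). These included Frmd4a 0.80 ± 0.11, Cemip2 0.85 ± 0.13, Cnksr3 0.74 ± 0.12 and Itpr2 0.55 ± 0.11. Of 25 late mature genes 14 fell and 0 rose (16 fell adjusted over the list alone; adjusted p = 3.56e-14, adjusted p = 0.0599 with an estimated correlation). Among them were Apod -1.46 ± 0.16, Gsn -1.32 ± 0.16, Ppp1r14a -1.16 ± 0.14 and Klk6. Of 25 myelin protein genes 8 fell and 2 rose (12 fell and 7 rose adjusted over the list alone; adjusted p = 3.09e-05, adjusted p = 0.34 with an estimated correlation), with Opalin, Aspa -1.34 ± 0.17, Mal -1.36 ± 0.18 and Ermn -1.32 ± 0.18 down. Of 30 precursor genes 3 fell and 0 rose (3 fell adjusted over the list alone; adjusted p = 0.00354, adjusted p = 0.558 with an estimated correlation): C1ql1 -1.04 ± 0.28, Cspg5 -1.09 ± 0.29 and Megf11 -0.95 ± 0.28. All 3 calls ended without RalA cKO 1 (-0.77, -0.90 and -0.75) and without RalAB cKO 2, 3 or 4, and those of Cspg5 and Megf11 also without RalA cKO 3. Of 25 transcription factors Tcf7l2 0.59 ± 0.14, Zfp488 0.35 ± 0.10 and Nfatc2 0.89 ± 0.26 rose and Prrg1 -1.37 ± 0.30, a membrane protein kept in that list, fell (4 up and 1 down). The calls of Zfp488 and Nfatc2 ended in 6 and 7 of 12 runs with 1 library left out (0.30 and 0.78 without RalAB cKO 1).

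Of 24 cholesterol synthesis genes 15 were lower and 1 higher in RalAB cKO than in RalA cKO (19 fell and 1 rose adjusted over the list alone; adjusted p = 2.66e-11, adjusted p = 0.149 with an estimated correlation). Examples were Cyp51 -0.77 ± 0.12, Tm7sf2 -1.18 ± 0.19, Lss -0.72 ± 0.12 and Msmo1 -0.66 ± 0.12. Of 26 fatty acid and sphingolipid genes 9 fell and 0 rose (13 fell adjusted over the list alone; adjusted p = 2.5e-06, adjusted p = 0.204 with an estimated correlation). These included Acss2 -1.34 ± 0.14, Scd1 -1.31 ± 0.19, Cers2 -0.62 ± 0.12 and Fads2 -0.63 ± 0.13. Of 19 astrocyte genes 7 fell and 0 rose (12 fell and 1 rose adjusted over the list alone; adjusted p = 1.14e-06, adjusted p = 0.356 with an estimated correlation). Among them were Gjb6 -1.67 ± 0.38, Aldoc -0.58 ± 0.13, Gja1 -1.03 ± 0.24 and Mlc1 -0.78 ± 0.19. Of 18 neuron genes Tubb3 -1.33 ± 0.17 and Uchl1 -0.89 ± 0.14 fell and Elavl3 0.41 ± 0.11 rose (adjusted p = 0.0344, adjusted p = 0.603 with an estimated correlation), and the list call ended without RalA cKO 1 (adjusted p = 0.204), RalAB cKO 2 (adjusted p = 0.0787) or RalAB cKO 3 (adjusted p = 0.0809). Of 13 mitochondrially encoded genes mt-Co3 -0.72 ± 0.15 and mt-Nd3 -0.74 ± 0.18 fell (7 fell adjusted over the list alone; adjusted p = 9.96e-05, adjusted p = 0.356 with an estimated correlation). Smaller groups of calls were Flna 0.79 ± 0.14 and Pld1 0.53 ± 0.13 among Ral effectors, and Rab3d 1.14 ± 0.21, Rab27a 2.06 ± 0.42 and Vamp8 1.36 ± 0.30 up in vesicle traffic. Others were Edem1 0.38 ± 0.11 up and Xbp1 -0.50 ± 0.14 down, Btg2 1.82 ± 0.40 up and Phlda3 -0.59 ± 0.15 down, and the endothelial genes Itm2a 0.56 ± 0.14 and Eng 1.20 ± 0.36 with the Schwann cell list gene Fcgrt 1.43 ± 0.33 up. None of 28 cell cycle genes, 9 exocyst subunits, 28 oxidative phosphorylation genes, 10 pericyte and fibroblast genes (3 higher adjusted over the list alone), 5 ependymal genes or 6 erythroid genes was called between the mutants. Calls ended for Mlc1 without RalAB cKO 4 (-0.66), mt-Nd3 without RalA cKO 4 (-0.59), Pld1 without RalA cKO 2 (0.49), and in 3, 3, 5, 7 and 8 of 12 runs for Phlda3, Elavl3, Xbp1, Eng and Edem1 (-0.51 without RalA cKO 4, 0.37 without RalA cKO 1, -0.41 without RalA cKO 4, 0.98 without RalAB cKO 2 and 0.35 without RalA cKO 1). Of 94 genes followed, 75 kept their call in every planned setting that held them.

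Some genes changed in both mutants. Among 217 genes called in both, 199 moved in the same direction (130 higher and 69 lower), where independent calls would give 21.6 and 13. The sterol enzyme Lss and the matrix genes Nid1 and Mgp were lower in both mutants, and Ptgds, Klhl30, Cd63 and Pex5l were higher in both. Because both used the same controls, unchanged mutants were simulated 20 times, which gave a mean correlation of 0.503 (0.431 to 0.568). The observed 0.389 lay below this range, but changes in only 1 mutant also lower a correlation. It therefore cannot decide whether changes were shared beyond the common controls. The simulations gave 0 genes called in both mutants, although they held no real change in either. Measured over 9839 genes, the covariance was 0.0854 against a simulated 0.024, and 71.3% of genes had the same sign against 66.6%. With separate control mice for each mutant, 12 to 181 genes were called in both, and 11 to 104 moved in the same direction. With RalA cKO set against control mice 2 and 3, 104 of 181 did. The correlation was 0.0911 to 0.398. Of the 374 RalA cKO genes 318 had the same sign in RalAB cKO and 114 differed between the mutants. Of the RalAB cKO genes 1037 also differed from RalA cKO in the same direction.

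Genes that moved in opposite directions numbered 18, and all of them differed between the mutants. The latter is no separate support, because opposite changes from the same controls add up between the mutants. Of the microglia list, Ly86 (-1.90 and 1.48), Siglech (-1.53 and 0.89) and Itgam (-1.10 and 1.54) fell in RalA cKO and rose in RalAB cKO. The same was found for Cd180 (-1.06 and 1.77), Inpp5d (-1.23 and 1.63), Pik3ap1 (-1.14 and 1.65), Sla (-1.38 and 0.99), Il6ra (-1.36 and 1.29), Slco2b1 (-1.01 and 1.49), Ptk2b (-1.05 and 0.83), Efhd2 (-0.60 and 1.07), Grik3 (-0.48 and 0.32), 1700017B05Rik (-0.94 and 1.40) and Plekhf1 (-3.12 and 0.48). Opalin of the myelin list (0.72 and -0.41), Klk6 (0.97 and -0.71) and Ppp1r14a (0.59 and -0.57) of the late mature list and the cyclic AMP sensor Rapgef3 (0.59 and -0.41) rose in RalA cKO and fell in RalAB cKO.

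**Figure D4:**
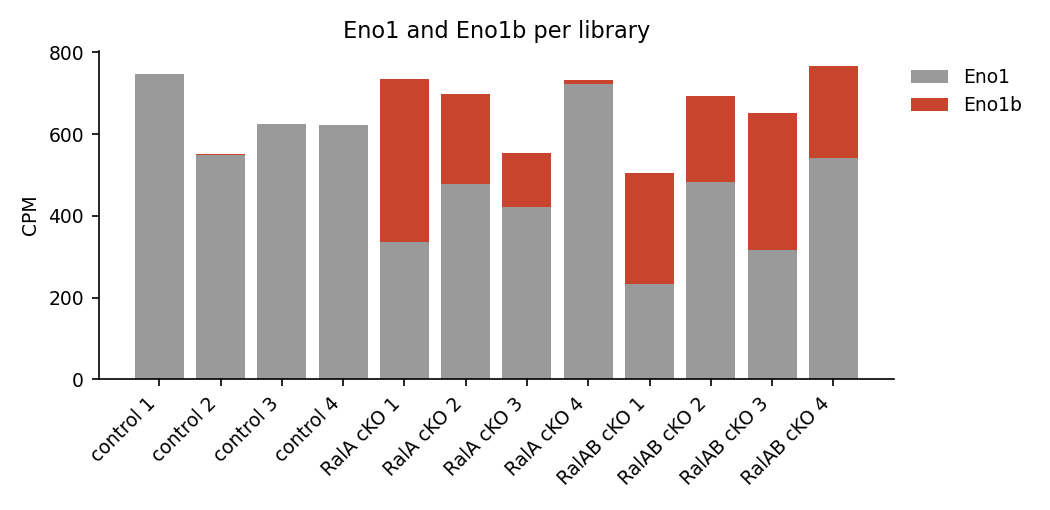
CPM of Eno1 and of its near-identical copy Eno1b, stacked, in each of the 12 libraries.

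**Figure D5:**
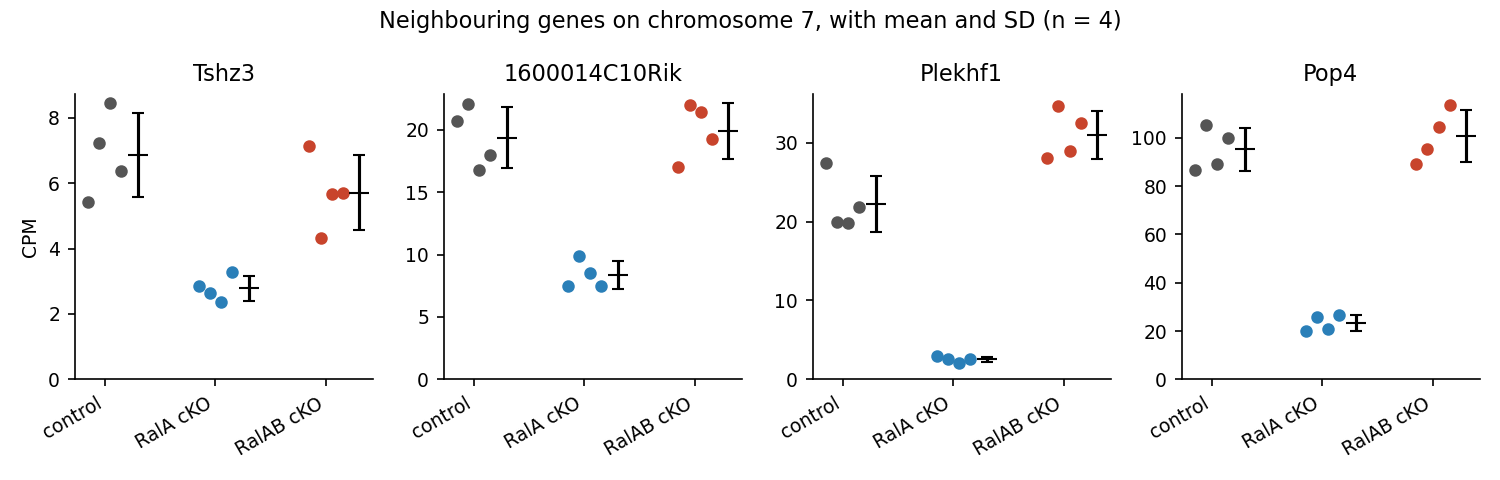
CPM of 4 neighbouring genes of chromosome 7 in each library, with mean and SD, n = 4 mice per group.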

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

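The tests of Eno1b, of microglial make-up and of chromosome 7 were chosen only after the results were seen, while the prediction for the divisions of libraries was written before they were run.

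A Dixon-type rule compared each library with the other 3 of its group for 197 genes and the quality measures, and 34 of 615 sets of 4 (5.53%) had a library apart, where chance sets apart about 1 in 20 (5%). In control 3, Aldoc (176 CPM), Cdkn1a (7.56 CPM), Mlc1 (42.5 CPM) and Slc6a11 (269 CPM) were high, and Klk6 (35.5 CPM), Lss (649 CPM) and the share of the 10 highest genes (13.1%) were low. Control 2 was high for Vegfa (58.2 CPM). RalA cKO 1 was high for Aurkb (12.2 CPM), C1ql1 (77.2 CPM), Gja1 (34.9 CPM), H2-D1 (28.0 CPM), Ier2 (19.0 CPM), Inpp5d (5.63 CPM), Nnat (126 CPM), Nr4a1 (18.3 CPM) and Ube2c (26.7 CPM), and low for Rala (33.1 CPM) and mt-Nd1 (1186 CPM). Zfp36 was low in RalA cKO 2 (19.7 CPM), and Ermn (268 CPM) and Vegfa (57.5 CPM) were high in RalA cKO 3. In RalA cKO 4, Ctsa (418 CPM), Exoc4 (92.4 CPM) and Sema3b (17.7 CPM) were high and Cd83 (3.06 CPM), Nfatc2 (2.56 CPM) and Pttg1 (6.62 CPM) were low. RalAB cKO 1 was high for Bst2 (9.21 CPM) and low for Phgdh (202 CPM), RalAB cKO 3 was high for Klk6 (48.1 CPM) and Mgst3 (17.7 CPM), and RalAB cKO 4 was low for Serpinb1a (2.81 CPM) and the share of counts of the reactive microglia list (0.0672%). The total was near the chance share, but 11 of the 34 lay in RalA cKO 1, 7 in control 3 and 6 in RalA cKO 4. No library was removed for them.

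The 18 genes with opposite directions in the mutants stood out because the same controls served both. In each comparison 1 of the 35 divisions reached the real count, namely the real one, with 374, 2478 and 1551 genes against 2, 1637 and 1 for the highest other. No arbitrary division therefore reached the counts, though 1 in 35 is the smallest share these divisions allow. The other divisions mix the genotypes, which widens the spread within groups and lowers their counts. For RalAB cKO a wrong grouping still gave 1637 genes.

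Eno1b averaged 0.496 CPM in control, 190 CPM in RalA cKO (11.2 to 397) and 260 CPM in RalAB cKO, while Eno1 averaged 636, 489 and 394 CPM. Added together, the copies differed from control by 0.0947 ± 0.138 in RalA cKO and 0.0386 ± 0.138 in RalAB cKO. A true rise of Eno1b with Eno1 unchanged would have needed 0.377 and 0.494, above the upper limits (2 standard errors) of 0.370 and 0.314. The Eno1b result may thus reflect reads divided differently between the copies, for example through a sequence variant carried by the mutant mice. Sequence reads were not used here, so the origin stays open.

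Microglial genes in RalAB cKO may come from more microglial RNA among the sorted cells, from reactive microglia, or from both. The reactive list minus the microglia list was -2.87 ± 0.184 in control and -1.92 ± 0.128 in RalAB cKO (mean log2 CPM ± SD, n = 4), a difference of 0.953 (exact permutation p = 0.0286, the smallest value 70 divisions allow). In RalA cKO it was already -2.14 ± 0.252 (exact permutation p = 0.229 against RalAB cKO), although microglia genes were lower there. The measure thus also moved without a rise of microglia genes. Of the 12 reactive genes 5 averaged under 1 CPM in control, and such low values would damp their rise rather than enlarge it. They therefore do not account for the difference from control. A measure resting partly on such genes cannot decide, so more microglial RNA of unchanged make-up stays open. The share of counts rose from 0.0552% to 0.0716% for the reactive list and from 0.0572% to 0.219% for the microglia list. Such a sum follows the most abundant members of a list. The median member rose 9.10-fold in the reactive list and 3.94-fold in the microglia list. A stress response during cell preparation could also raise immediate early genes, whose median was 0.902, and bulk RNA cannot tell these apart.

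Tshz3, 1600014C10Rik, Plekhf1 and Pop4, neighbours on chromosome 7 between 36698118 and 38271423, were all lower in RalA cKO (-1.30, -1.21, -3.12 and -2.03). They made up 4 of 8 tested genes there (permutation p = 0.008 over 5 stretch lengths and 5000 gene orders), although fixed windows of 5 Mb gave 4 of 23 genes and an adjusted p of 0.724. Plekhf1 was at most 2.95 CPM in RalA cKO and at least 19.8 CPM in every other library. Against control the median of the 4 genes in RalAB cKO was 0.0601, so loss of RalA acting whether or not RalB is present did not explain them. An effect of RalA loss that needs RalB to be present cannot be judged from this comparison. A local genomic difference in the RalA cKO mice may underlie this stretch, and DNA was not analysed here.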

How the results depend on the processing

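Other ways to test were written before the data were examined, and only the removal of 3 libraries with both Xist and Y-linked reads was chosen after the result was seen. That removal left 3 mice per group, so its smaller counts also reflect fewer mice. RalA cKO changed 374 genes in the planned test, 1083 with DESeq2, 1789 with limma-voom quality weights, 232 with mouse number as a block, 111 with the Y-linked covariate and 31 without the 3 libraries; leaving out 1 library gave 85 (RalA cKO 4), 103 (control 2), 154 (control 3), 176 (RalA cKO 2) and 248 (control 4) to 677 (RalAB cKO 1) and 947 (control 1). RalAB cKO changed 2478 genes, 4071 with quality weights, 1006 without the 3 libraries and 1605 to 3209 leaving out 1. Between the mutants the 1551 became 2541, 727 and 1117 to 1678. No call that stayed past the threshold changed direction in any setting. None of the called genes followed through the settings did so either, past the threshold or not. With the Y-linked covariate 27 of 53, 100 and 86 of 94 followed genes kept their call in the 3 comparisons, and 12, 78 and 69 did without the 3 libraries. Leaving out RalA cKO 4 or control 2 ended 29 and 26 of the 53. Eno1b was called in neither mutant with limma-voom, with or without quality weights, nor in RalA cKO when only its 8 libraries were fitted. Mouse numbers did not pair the libraries: mice of the same number had a mean correlation of -0.0137 (n = 12 pairs).

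Rala in RalA cKO was -0.58 with length offsets (adjusted p = 0.0305). In RalAB cKO it was -0.63 with offsets (adjusted p = 0.00397), -0.53 with quality weights (adjusted p = 0.00624), and -0.52 (without control 1, adjusted p = 0.012) to -0.29 leaving out 1 library. Its short transcript was -3.26 in RalA cKO as a bound and -5.46 in RalAB cKO from summed counts. The length offsets are not independent of that transcript. Its most abundant transcript did not pass (edgeR adjusted p = 0.417 in RalA cKO and 0.206 in RalAB cKO). Ralb between the mutants was -0.0351 with the Y-linked covariate (adjusted p = 0.941) and -0.0317 (without RalA cKO 3) to 0.10 leaving out 1. Lists past the threshold numbered 14, 11 and 15, with an estimated correlation 0, 0 and 3, and with fry 3, 13 and 14 by direction and 16, 24 and 23 by mixed tests. With a block they numbered 14, 11 and 16. The 199 shared genes became 604 at an adjusted p under 0.1, and 31, 26, 11, 104, 43 and 25 when RalA cKO was set against control mice 1 and 2, 1 and 3, 1 and 4, 2 and 3, 2 and 4, and 3 and 4.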

Other observations

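The tests by chromosome position and the reading of sex-linked genes per library were chosen only after the result was seen. Genes next to the targets also changed. Nid1, 4.44 Mb from Rala, fell by 2.37 in RalA cKO and 3.01 in RalAB cKO. Near Ralb, the activin subunit Inhbb (-1.79), the synaptic organizer C1ql2 (-1.43) and the cytoskeletal linker Epb41l5 (-0.87) fell in RalAB cKO, and the iron reductase Steap3 (1.51) and Tmem37 (1.83) rose, all within 1 Mb. Clasp1, a microtubule protein 0.987 Mb from Ralb, fell in RalA cKO (-0.74), although RalB was not targeted there. Hist1h4k, a histone gene with close copies, was 4.00 higher in RalA cKO and 4.81 higher in RalAB cKO and is uncertain.

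As a group, genes within 10 Mb of a target were not called more often than elsewhere. Around Rala 3 of 74 genes changed in RalA cKO (Fisher's exact p = 0.462), 14 in RalAB cKO (exact p = 0.881) and 7 between the mutants (exact p = 0.716). Around Ralb they were 1, 7 and 4 of 34 (exact p = 0.617, 0.663 and 1). In 477 windows of 5 Mb per comparison, mitochondrial DNA stood out in RalA cKO (7 of 13, adjusted p = 8.59e-06 by an exact 1-sided hypergeometric test). Between the mutants the window at 170000001 to 175000000 of chromosome 1, which holds Fcer1g, stood out with 18 of 49 genes (13 higher and 5 lower, adjusted p = 0.00191 by the same exact test). This test counts genes as independent, so genes that vary together make its p-values too small. The mitochondrial window repeats the mitochondrially encoded list, whose estimated correlation was 0.592 (camera adjusted p = 0.266 with that correlation).

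Xist, transcribed from the inactive X of females, and the Y-linked gene Ddx3y varied within every group. Xist was 1.77, 124, 173 and 68.9 CPM in control, 0.45, 215, 0 and 0.19 CPM in RalA cKO and 434, 163, 9.75 and 0 CPM in RalAB cKO. Ddx3y was 15.7, 4.56, 0.21 and 0.09 CPM in control, 16.7, 3.01, 35.7 and 24.5 CPM in RalA cKO and 0, 0, 15.3 and 14.8 CPM in RalAB cKO. Both were present in control 2, RalA cKO 2 and RalAB cKO 3. RNA of more than 1 mouse may be present in these libraries. Without them 31 genes changed in RalA cKO and 1006 in RalAB cKO. Each group then held 3 mice, and fewer mice alone can lower such counts. Leaving out only RalA cKO 4 gave 85 genes in RalA cKO. Control held mostly Xist-bearing libraries and RalA cKO mostly Y-bearing ones, so sex may contribute to the RalA cKO difference, where the Y-linked covariate left 111 genes.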
